A study of Mus musculus with 6 samples.

How the data were processed

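The series holds 6 two-channel arrays from the anterior lobe of the pituitary of pregnant C57Bl/6J mice at gestation day 17 to 18. Per the labels, 3 pools of 12 glands each were independent biological replicates, and each pool was hybridised to a set of 2 promoter tiling array designs. DNA recovered with an antibody against POU1F1 (PIT-1) carried Cy5 and the matching input DNA carried Cy3. Per the labels' protocols, nuclei were cross-linked, chromatin was sonicated to a mean fragment size of 500 bp, and ChIP DNA was amplified by ligation-mediated PCR before labelling. No array of a control antibody was used here, so input is the only comparison. The labels describe no dye swap.

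The deposited scanner files give a linear intensity per probe at 635 nm (Cy5, ChIP) and 532 nm (Cy3, input), extracted with NimbleScan 2.3.78 on a design of mouse build mm8, per the file headers. The authors' processed table gives a log2 value per probe. Set against the scanner files, 100% of its values on every array equalled log2 of Cy5 over Cy3 minus a constant per array, within 0.0051, which fixes the direction of the ratio as ChIP over input. The authors' peak lists, made per array, give each peak a height on the log2 scale, a false discovery rate (a q-value, up to 0.2 when rounded, in the deposited lists) and a distance in bp to transcription starts. The peak caller's settings are not given in the sources used here. Between 61.5% and 76.9% of the deposited peak heights per list, among peaks with at least 4 probes, equalled the 4th highest probe log2 ratio within 0.015, and a height is used here only to describe and rank peaks. In some lists several peaks of a chromosome share its highest height (6 peaks on chromosome 7 in pool 2), so that the heights of the strongest peaks have no order.

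From the scanner signals, log2(ChIP/input) was computed for each of 385301 promoter probes on design 1 and 385507 on design 2 and centred on the array median, without loess. Probe ratios were averaged in adjoining 500 bp windows laid from the first probe of each tiled region, with at least 4 probes. This left 70902 windows on design 1 and 70892 on design 2, with a median of 5 probes. The mean of the 3 pools was tested against 0 per design with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the windows of a design, and windows with an adjusted p under 0.05 were called enriched (above 0) or depleted (below 0). Counts were added over the designs. ChIP and input of a pool lay on the same array, so the ratio pairs them, and an unpaired fit was an alternative. The number of arrays limits the precision of every value. Median input signal per array ran from 1102 to 1626, and 33.7% to 53.2% of promoter probes lay above the 95th percentile of the random-sequence control probes in the input channel. The fit was tested on simulated data with the windows of each design and 3 pools. It recovered 96% (design 1) and 90% (design 2) of 50 windows with a log2 ratio of 0.5, and 8% and 2% at 0.25. In the simulation 70702 of 70902 and 70692 of 70892 windows had no ratio. Far more windows were called in the data, where the Benjamini-Hochberg cutoff is therefore less strict. The recovered shares are not detection rates for the data.

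Genes were named through the authors' peak lists: a gene was linked to a tiled region if any deposited peak in that region was mapped to it, and all windows of its linked regions were taken as its windows. Of 8174 names in the lists, 7829 matched the RefSeq gene table (assembly GRCm38.p6, used for names only) by gene identifier, 2215 were updated to the current symbol, and 8171 symbols remained. Regions without a deposited peak therefore have no gene name here. Positions are those of the deposited files (mm8). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for lists, peaks and figures.

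The 18 gene lists, the tests and the rule for named genes were written before the data were examined. The lists are POU1F1 targets, other anterior pituitary lineages, pituitary transcription factors, hormone and releasing factor receptors, secretory granule and exocytosis, cAMP and PKA signalling, JAK-STAT and prolactin signalling, cell cycle, ER stress and protein folding, cytosolic ribosomal proteins, oxidative phosphorylation, chromatin regulators, apoptosis, circadian clock, posterior and intermediate lobe or hypothalamus, blood, immune and endothelial cells, liver, muscle, skin and sperm genes, and olfactory and vomeronasal receptors. A gene's score was its highest window mean. A list's median score was compared with 100000 random lists drawn with replacement from the named genes within 5 bins of windows per gene (two-sided permutation test, Benjamini-Hochberg over the 14 lists with at least 5 named members). This test is conditional on a gene being named in a peak list. A share of all 21031 protein-coding genes with a RefSeq mRNA (two-sided Fisher's exact test, Benjamini-Hochberg over 18 lists) was added after the data were seen, and which of those genes the arrays tile is not known here. Tested on simulated data over 8171 genes, the list test called 5% of lists of 20 with no shift, 42.5% with 0.1 added and 100% with 0.3 added.

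Named genes are (1) members of the POU1F1 target, other lineage and transcription factor lists with an enriched window or a peak in at least 2 pools, plus Prl, Gh, Tshb, Pou1f1, Pomc, Lhb, Fshb and Cga whatever their values; (2) the 15 genes with the highest enriched window above 0 in all 3 pools; (3) the 10 genes with the highest lowest-of-3-pools peak height; and (4) in every other list the 3 members with the highest score among those with an enriched window. In (2) and (3) provisional symbols are skipped and a gene that shares a window with a neighbour is named with it. Of the genes this rule takes, 1 is not reported here. Shared peaks were counted by gene at a false discovery rate of 0.05 or less. Their chance overlap was drawn 100000 times over all tiled regions within a design. Alternatives covered background correction, loess, centring, scaling, dim probes, window length, probe median, thresholds, the variance prior, the pairing of the channels, peak overlap, gene score and leaving out each pool. The search for the POU1F1 DNA element was not run, since it needs the genome sequence of this build, which was not used here. The peak lists number the precipitations 2, 3 and 4. Pool 1 is number 2 on both designs, while pools 2 and 3 are numbers 3 and 4 on design 1 and 4 and 3 on design 2. Pools follow the titles here. Following the numbers would exchange the values given for pools 2 and 3 on design 2, and would change values that join a pool over both designs, such as totals without a pool, list shifts without a pool, peaks per pool over chemoreceptor genes and the profile per pool around transcription starts.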

Results

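Binding of POU1F1, the pituitary transcription factor required for somatotrophs, lactotrophs and thyrotrophs, was measured by chromatin immunoprecipitation on promoter arrays in the anterior pituitary of mice late in pregnancy. The 3 pools of 12 glands were each hybridised to array designs 1 and 2, which carry different promoters, giving 6 arrays of ChIP DNA against input DNA. Between 33.7% and 53.2% of promoter probes per array had an input signal above the 95th percentile of control probes, and the number of arrays limits the precision. Values are mean log2(ChIP/input) ± SD over the pools (n = 3), adjusted p-values are from limma, and positions are in mouse build mm8.

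The first question was whether promoters known to be driven by POU1F1 were recovered. The gene encoding POU1F1 itself had among the highest ratios on the arrays: the window over the listed transcription start of Pou1f1 (chromosome 16, 65438611 to 65439110) stood at 2.04 ± 0.18, 4.1-fold above input (adjusted p = 2.45e-06). The hormone promoters followed. Gh, growth hormone (chromosome 11, 106117650 to 106118149, over the start), was at 1.18 ± 0.17 (adjusted p = 2.25e-05). Prl, prolactin (chromosome 13, 27064790 to 27065289, over the start), was at 0.96 ± 0.18 (adjusted p = 9.76e-05), and Tshb, the thyrotropin beta subunit (chromosome 3, 102912025 to 102912524, centred 500 bp upstream of the start), was at 0.54 ± 0.18 (adjusted p = 0.000111).

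Along these regions enrichment was local. In Pou1f1 the windows 500 bp to either side of the start were at 0.43 ± 0.10 upstream and 0.60 ± 0.10 downstream, and the 5 windows farther upstream lay between 0.05 and 0.09 and did not pass. In Prl the window centred 500 bp upstream was at 0.59 ± 0.22 and the one 500 bp downstream at 0.34 ± 0.06. In Gh the window 500 bp upstream was at 0.61 ± 0.24, while that 500 bp downstream was at 0.13 ± 0.13 and did not pass. A window centred 2500 bp upstream of Prl was at 0.70 in pool 1, -0.57 in pool 2 and -0.01 in pool 3.

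**Figure D1:**
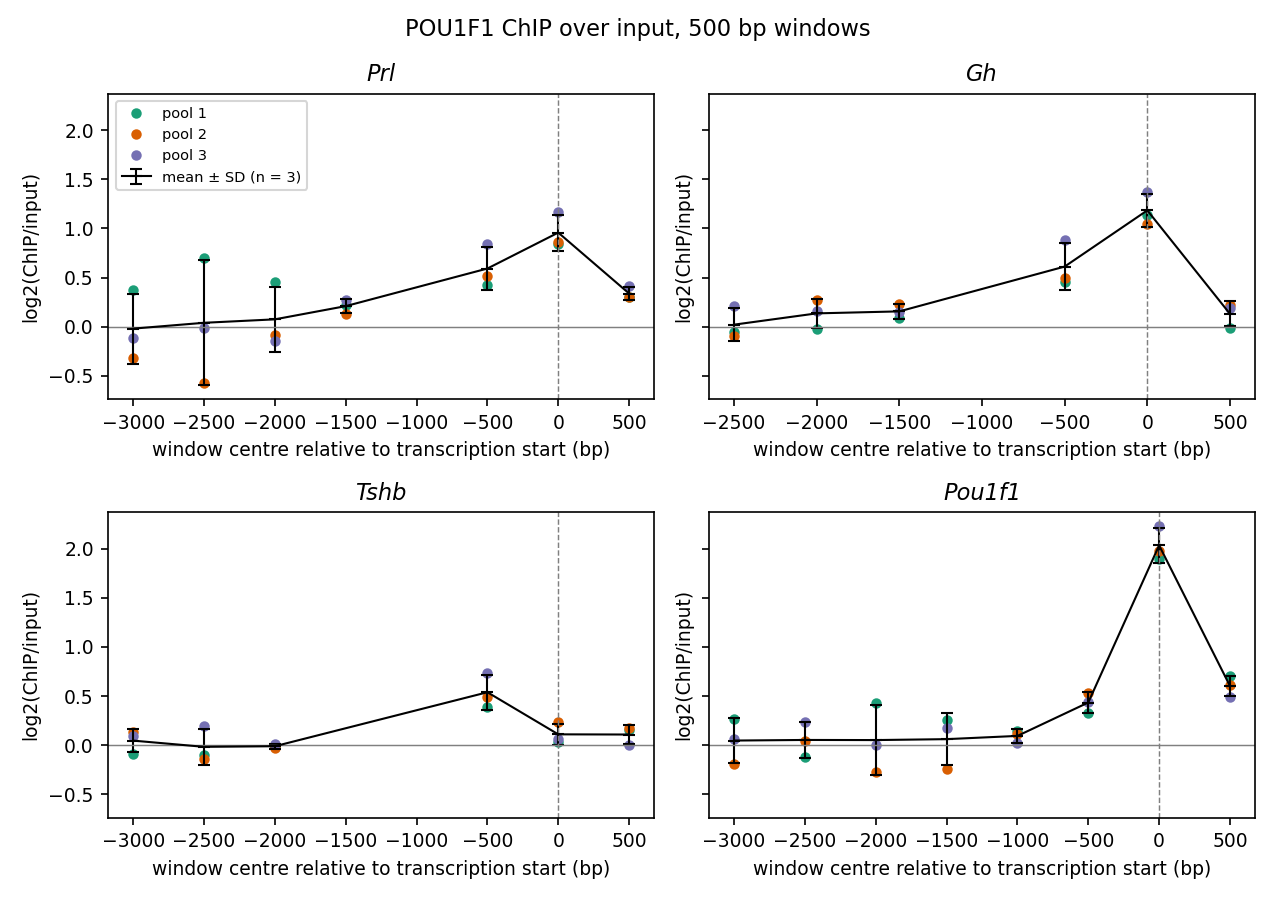
Mean log2(ChIP/input) of 500 bp windows (vertical axis) by distance of the window centre from the listed transcription start in bp (horizontal axis, upstream negative) for Prl, Gh, Tshb and Pou1f1. Points are the 3 pools, and the black line joins tested windows with the mean and SD (n = 3); the window over the start is the highest in Pou1f1 at 2.04, in Gh at 1.18 and in Prl at 0.96, while in Tshb the highest, 0.54, is centred 500 bp upstream.

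Of 16 genes listed as POU1F1 targets, 11 were named in a peak list, and all 11 had an enriched window (also 11 adjusted over the list alone). Of all 8171 named genes, 69.0% had one, and this difference did not pass (Fisher's exact test among named genes, adjusted p = 0.133). Besides the hormones and Pou1f1, Thrb, the thyroid hormone receptor beta, stood at 1.07 ± 0.08, Ghrhr, the receptor for growth hormone releasing hormone, at 0.63 ± 0.30 and Nr1d1, a nuclear receptor of the circadian clock, at 0.55 ± 0.17. Neurod4 was at 0.43 ± 0.07, Prlr, the prolactin receptor, at 0.38 ± 0.04, and the retinoic acid receptors Rara and Rarb at 0.36 ± 0.08 and 0.32 ± 0.18. Gh, Prl, Pou1f1 and Thrb were the 4 members with a peak in all 3 pools, 25% of the list against 3.23% of 21015 other protein-coding genes (Fisher's exact test, adjusted p = 0.00881). The median score of the 11 members was 0.55 against 0.31 in random lists of the same window numbers (permutation test, adjusted p = 0.0299). That call was lost with the median of probes (adjusted p = 0.0889), without pool 3 (adjusted p = 0.0597) and without matching on windows (adjusted p = 0.063). With ChIP and input taken as unpaired, the windows of Ghrhr, Neurod4, Prlr, Rara, Rarb and Tshb were no longer called, and without pool 3 those of Neurod4, Prlr, Rara and Rarb. Rarb was also lost without pool 2, with 300 bp windows and with the median of probes, and Rara with 1000 bp windows.

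Genes listed for the corticotroph and gonadotroph lineages were set beside these. Those lineages do not express POU1F1, but not every listed gene, Cga and Pcsk1 among them, is confined to them. Of 14 such genes, 1 was named in a peak list: Pcsk1, the prohormone convertase, which also serves other endocrine cells, at 0.72 ± 0.04 with a peak in all 3 pools (1 gene also adjusted over the list alone). The corticotroph hormone gene Pomc and the gonadotropin subunit genes Lhb, Fshb and Cga were not named in the lists used here, so their ratios were not analysed here. Among 25 pituitary transcription factors, 12 were named and 9 had an enriched window (10 adjusted over the list alone). Insm1 stood at 0.84 ± 0.21, Pax6 at 0.74 ± 0.26, Zeb2 at 0.72 ± 0.16 and Eya1 at 0.45 ± 0.20. Lhx3 was at 0.25 ± 0.05, Six6 at 0.25 ± 0.07 and Sox2 at 0.23 ± 0.09. The listed symbol Sf1, at 0.64 ± 0.03, names splicing factor 1 in these files, not the steroidogenic factor. As the list was fixed beforehand, Sf1 is counted among the 25, the 12 and the 9 and in the list's median score. The factor list's median score did not differ from random lists (permutation test, adjusted p = 0.868). The calls of Lhx3, Six6 and Sox2 were lost without pool 2 and without pool 3, and that of Sox2 also after loess and after normexp.

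Over all promoters, enrichment was far more frequent than depletion. The highest named window was at Gsap (chromosome 5, 20696928 to 20697427, centred at -900 bp from the start), at 2.65 ± 0.20 or 6.29-fold (adjusted p = 3.27e-12). It was followed by Zfp384, a zinc finger factor (chromosome 6, 124974144 to 124974643), at 2.51 ± 0.27 and by Ell, a transcription elongation factor (chromosome 8, 73467940 to 73468439), at 2.15 ± 0.52. After Pou1f1 came Blcap at 2.00 ± 0.41, Ube2s, a ubiquitin-conjugating enzyme, at 1.98 ± 0.40 and Crlf2, a cytokine receptor, at 1.94 ± 0.30. Gabarapl2, an autophagy protein, was at 1.88 ± 0.55, Zfp658 at 1.84 ± 0.34 and Esrra, an orphan nuclear receptor of energy metabolism, at 1.76 ± 0.14. The phosphodiesterase Pde9a stood at 1.72 ± 0.10, the neighbours Gtpbp1 and Josd1, which share a window, at 1.69 ± 0.14, the histone deacetylase Hdac9 at 1.68 ± 0.10 and Plekhg2 at 1.68 ± 0.30. With an intensity trend and robust prior in limma, the windows of Ell, Gabarapl2 and the chromatin remodeller Chd4 were no longer called.

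In all, 8421 of 141794 windows (5.94%) were enriched and 1063 depleted, so 88.8% of calls lay above input. The enriched windows had a median log2 ratio of 0.35, and 8396 of them were above 0 in every pool. The depleted windows had a median of -0.26 and a lowest value of -0.83. On design 1, 5145 windows were enriched and 796 depleted, and on design 2, 3276 and 267. The enriched windows fell in 5476 of 21623 tested regions. Of these regions 4583 held a named gene, which gave 5634 genes with an enriched window. A log2 ratio of at least 0.5 was reached by 1700 enriched windows. After loess within arrays 12463 windows were enriched and 3390 depleted, so that 78.6% of calls lay above input. Without 1 pool the count ran from 4040 (without pool 3) to 14029 (without pool 1). It was 1328 with ChIP and input unpaired and 16092 with loess and pool 1 left out.

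Peaks called by the authors in each pool separately gave a narrower set. At a false discovery rate of 0.05 or less, 728 genes had a peak in all 3 pools, and 727 of them also had an enriched window. The 10 genes with the highest lowest-of-3-pools peak height were Ccl17, a chemokine, Ell, Crlf2, Gsap, Plekhg2, Vamp1, a vesicle SNARE protein, Zfp384, Blcap, Zfp658 and Gabarapl2, with lowest heights between 1.45 and 1.53. These heights sat at a ceiling: the peaks of Ccl17 and Ell on chromosome 8 shared the highest height of that chromosome in every pool, 1.56, 1.65 and 1.53, and the peaks of all 10 but Zfp658 and Gabarapl2 were at their chromosome's highest in all 3 pools. No order among them is read from the heights. All 10 lay on design 1, and the highest height differed between chromosomes. On design 2 the peaks of Pou1f1 were also at the highest of chromosome 16 in every pool, at 1.04, 1.31 and 1.4. The heights therefore do not rank the 10 above Pou1f1 or other promoters of design 2. The best tested window of Vamp1 was at 1.35 ± 0.36. The peak of Ccl17 lay where fewer than 4 probes fell in a window, and its best tested window was at 0.25 ± 0.13.

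Pool 1 had 524 genes with a peak on design 1 and 575 on design 2. Pool 2 had 2331 and 2229, and pool 3 had 1473 and 1726. Of the tiled regions, 310 on design 1 and 284 on design 2 carried a peak in all 3 pools, where 8.56 and 10.9 were expected by chance (permutation test, p = 1e-05 for both, the smallest that 100000 draws can give). These regions were 69.2% and 56.7% of the regions with a peak in pool 1. The draws took every tiled region as equally likely to carry a peak, though regions differ in their number of windows. The same probes were used in every pool, so the p-values speak only against this chance model. Leaving out pool 1 raised the count of shared genes to 2653.

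Promoters with a peak in 1 pool were then measured in the other pools. At peaks of pool 2 on design 1, the median log2 ratio was 0.25 in pool 1 and 0.38 in pool 3, and 93.8% and 98.5% of the 2274 windows were above 0. At peaks of pool 3 on design 2, the medians were 0.26 in pool 1 and 0.46 in pool 2. The peaks of pool 1 transferred less evenly. On design 1 their median was 0.51 in pool 2 and 0.42 in pool 3, while on design 2 it was 0.10 in pool 2, where 54.2% of windows were above 0, and 0.17 in pool 3. Medians of windows without a peak lay between -0.01 and 0.00. Across windows, which are not independent replicates, Pearson's r between pools 2 and 3 was 0.661 on design 1 and 0.686 on design 2. Between pools 1 and 3 it was 0.488 and 0.443, and between pools 1 and 2 it was 0.413 and 0.227. Spearman's rho for the same pairs was 0.492 and 0.535, 0.362 and 0.299, and 0.238 and 0.0884.

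Large shares of some lists of genes used by most cells had an enriched window, and a gene without a deposited peak counts in these shares as having none. Of 60 cytosolic ribosomal protein genes, 50 were named and 43 had an enriched window (47 adjusted over the list alone), 71.7% of the list against 25% of other protein-coding genes (Fisher's exact test, adjusted p = 4.59e-13). A peak in all 3 pools was carried by 9, 15% of the list against 3.21% (Fisher's exact test, adjusted p = 0.00115). Peaks in all 3 pools were thus not particular to the POU1F1 targets. Rps14 led at 1.58 ± 0.13, with Rps3 at 0.74 ± 0.17 and Rps9 at 0.73 ± 0.23. Of 59 oxidative phosphorylation genes, 51 were named and 41 had an enriched window (47 adjusted over the list alone; Fisher's exact test, adjusted p = 6.21e-12), led by Cox6a1 at 1.03 ± 0.14, Uqcrh at 0.87 ± 0.35 and Uqcrq at 0.86 ± 0.35. Uqcrh shares its window with Lrrc41 and Uqcrq with Gdf9. Of 28 genes of ER stress and protein folding, 22 were named and 19 had an enriched window (22 adjusted over the list alone; Fisher's exact test, adjusted p = 1.1e-05). The ER chaperones Hsp90b1, at 1.13 ± 0.17 in a window shared with Ttc41, and Calr, at 0.62 ± 0.25, and the stress sensor Ern1, at 0.68 ± 0.07, led these. Among named genes alone, the shares with an enriched window did not pass in any of the 3 lists (Fisher's exact test, adjusted p = 0.0763 for ribosomal proteins and 0.313 for the others).

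Among named genes the ribosomal protein list had a median score of 0.41 against 0.32 in matched random lists (permutation test, adjusted p = 0.0299), a call lost after loess (adjusted p = 0.0966), without the dimmest probes (0.31, with the shift down from 0.09 to 0.05), with the median of probes (0.0854), without pool 2 (0.056) and without matching on windows (0.063). The oxidative phosphorylation list, at 0.37, and the protein folding list, at 0.39, did not pass (permutation test, adjusted p = 0.344 for both). The protein folding list passed with 1000 bp windows (adjusted p = 0.0395), 300 bp windows (0.033) and the mean of all windows as score (0.0367). The circadian clock list had a median of 0.50 against 0.32 (permutation test, adjusted p = 0.0469). Of its 21 genes, 14 were named and 11 had an enriched window (14 adjusted over the list alone), with the PAR bZIP factors Dbp at 0.78 ± 0.30 and Tef at 0.74 ± 0.15 and the period gene Per1 at 0.70 ± 0.31 the highest. That call was lost without any 1 of the pools (adjusted p = 0.144, 0.11 and 0.107 without pools 1, 2 and 3) and with the median of probes, where the shift went from 0.17 to 0.08 (adjusted p = 0.394). It was also lost with 300 bp windows (adjusted p = 0.264), normexp (0.124), loess (0.0714), no matching on windows (0.0672) and scaled arrays (0.05005). The shift itself was 0.12 with 300 bp windows and stayed at 0.17 with normexp, loess, no matching and scaled arrays. Without pools 1, 2 and 3 it was 0.16, 0.13 and 0.14.

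The signalling and secretory lists did not differ from matched random lists. Of 31 secretory granule and exocytosis genes, 16 were named and 12 had an enriched window (13 adjusted over the list alone; permutation test, adjusted p = 0.344). The synaptotagmin Syt4 was at 1.13 ± 0.12, Pcsk1 at 0.72 ± 0.04 and the granin Scg2 at 0.61 ± 0.31. Of 31 cAMP and PKA signalling genes, 14 were named and 11 had an enriched window (12 adjusted over the list alone; permutation test, adjusted p = 0.868), led by the phosphodiesterase Pde4b at 0.81 ± 0.12, the factor Crem at 0.78 ± 0.30 and the cyclase Adcy6 at 0.58 ± 0.04. Of 28 JAK-STAT and prolactin signalling genes, 16 were named and 10 had an enriched window (11 adjusted over the list alone; permutation test, adjusted p = 0.344). The inhibitor Socs1 was at 0.91 ± 0.23, the phosphatase Ptpn6, which shares its window with Grcc10, at 0.75 ± 0.19 and Stat3 at 0.46 ± 0.18. Of 38 hormone and releasing factor receptors, 12 were named and 8 had an enriched window (11 adjusted over the list alone; permutation test, adjusted p = 0.754), with Thrb, Rxrg at 0.68 ± 0.21 and Ghrhr the highest.

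Of 45 cell cycle genes, 23 were named and 20 had an enriched window (23 adjusted over the list alone), a share of 44.4% of the list (Fisher's exact test, adjusted p = 0.0117; 0.313 among named genes alone), though the median score did not pass (permutation test, adjusted p = 0.344). The replicative helicase subunit Mcm4 was at 1.05 ± 0.29 in a window shared with Prkdc, E2f3 at 0.69 ± 0.20 and Trp53 at 0.68 ± 0.13 in a window shared with Wrap53. Of 50 chromatin regulators, 29 were named and 18 had an enriched window (22 adjusted over the list alone; permutation test, adjusted p = 0.764), with Hdac9, Satb1 at 0.84 ± 0.08 and Chd4 at 0.73 ± 0.45 the highest. Of 37 apoptosis genes, 11 were named and 7 had an enriched window (10 adjusted over the list alone; permutation test, adjusted p = 0.64), led by Birc2 at 0.45 ± 0.15 and by Bax and Casp9, both at 0.40, with SDs of 0.17 and 0.22. Casp9 shares its window with Dnajc16.

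Genes of other tissues were named in a peak list less often than other genes, and without a deposited peak they count here as having no enriched window. Of 34 liver, muscle, skin and sperm genes, 3 were named, 8.82% of the list against 36.4% of other protein-coding genes (Fisher's exact test, adjusted p = 0.00174), and 1 had an enriched window (2 adjusted over the list alone; adjusted p = 0.516 among named genes). That gene, Apoa2, at 0.62 ± 0.13, shares its window with Tomm40l. Of 24 blood, immune and endothelial genes, 3 were named, 12.5% against 36.4% (Fisher's exact test, adjusted p = 0.0316) and 1, Cd68 at 0.36 ± 0.07 in a window shared with Mpdu1, was enriched (1 adjusted over the list alone; adjusted p = 0.516 among named genes). Of 20 genes of the posterior and intermediate lobe or hypothalamus, 1 was named, 5% against 36.4% (Fisher's exact test, adjusted p = 0.00508) and 0 had an enriched window (0 adjusted over the list alone; adjusted p = 0.621 among named genes). Of 1461 protein-coding olfactory and vomeronasal receptor genes, 335 were named (22.9% against 37.3%; Fisher's exact test, adjusted p = 9.01e-29) and 12 had an enriched window (7 adjusted over the list alone). With symbols outside that set, 345 were named. Their median score of 0.08 lay below the 0.32 of matched random lists (permutation test, adjusted p = 0.00028). The shift of -0.24 became -0.36 without pool 1, -0.08 without pool 2 and -0.21 without pool 3, and 339 of the 345 were named through a peak of pool 1. Olfr320 at 0.85 ± 0.05, Olfr56 at 0.68 ± 0.20 and Vmn2r57 at 0.63 ± 0.13 were the highest.

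**Figure D2:**
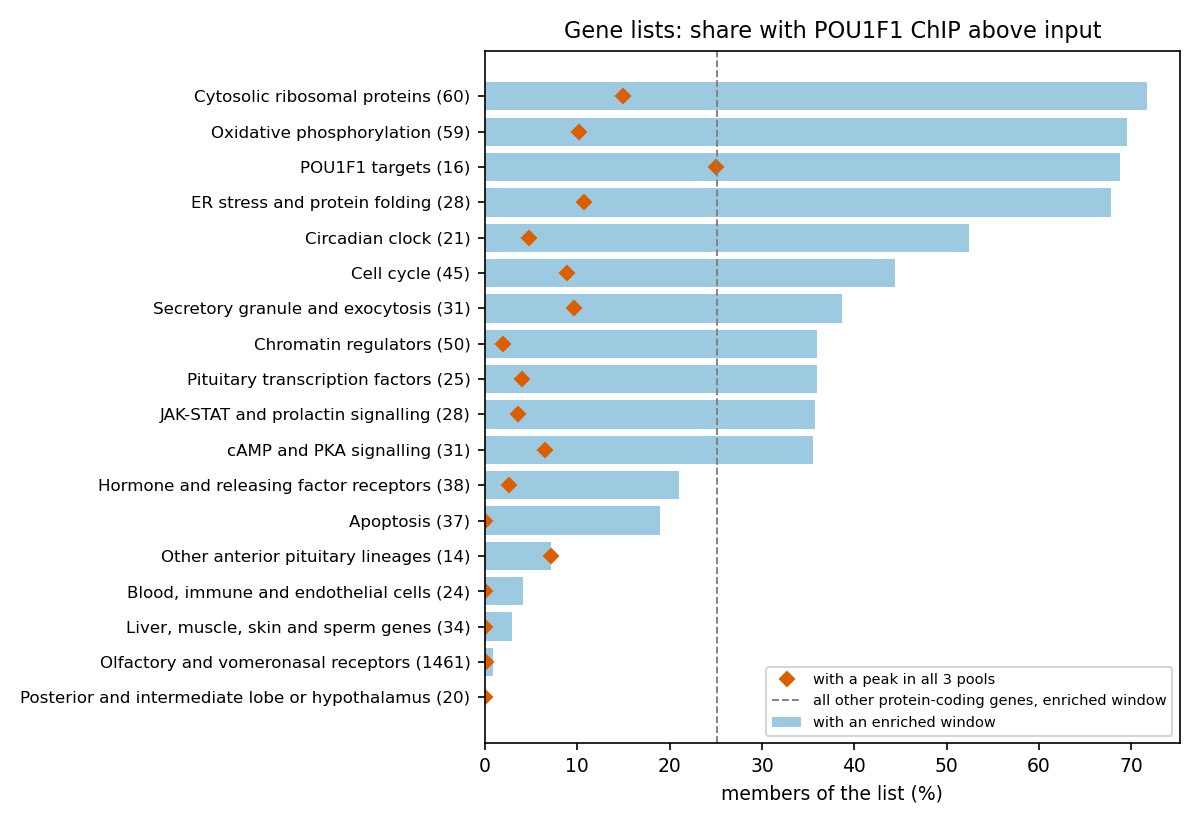
Percent of the protein-coding members of each gene list (horizontal axis; list size in brackets on the vertical axis) with an enriched window (bars) and with a peak in all 3 pools (diamonds), where a gene without a deposited peak counts as having neither; the dashed line marks the share of other protein-coding genes with an enriched window. Bars run from 71.7% for cytosolic ribosomal proteins to 0% for posterior lobe genes, and the highest diamond, 25%, belongs to the POU1F1 targets.

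Enriched windows clustered just upstream of transcription starts. In tiled regions with a listed start, 36.6% of the 7701 windows centred within 500 bp upstream were enriched (95% Wilson interval 35.6% to 37.7%), and 23% of the 8561 windows centred within 500 bp downstream. The share was 18.8% from -1000 to -501 bp, 4.72% from -2500 to -2001 bp and 2.06% from 2000 to 2499 bp. The mean log2 ratio of the 500 bp just upstream was 0.15 in pool 1, 0.25 in pool 2 and 0.22 in pool 3. From -2500 to -2001 bp it was 0.05, 0.00 and 0.02. Of all enriched windows with a listed start, 63.7% lay within 500 bp of it, against 26.8% of other windows (odds ratio 4.8). Windows are not independent replicates, and the regions are those in which the authors called a peak, so no p-value is given. The Wilson intervals take windows as independent and do not measure the spread between pools.

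**Figure D3:**
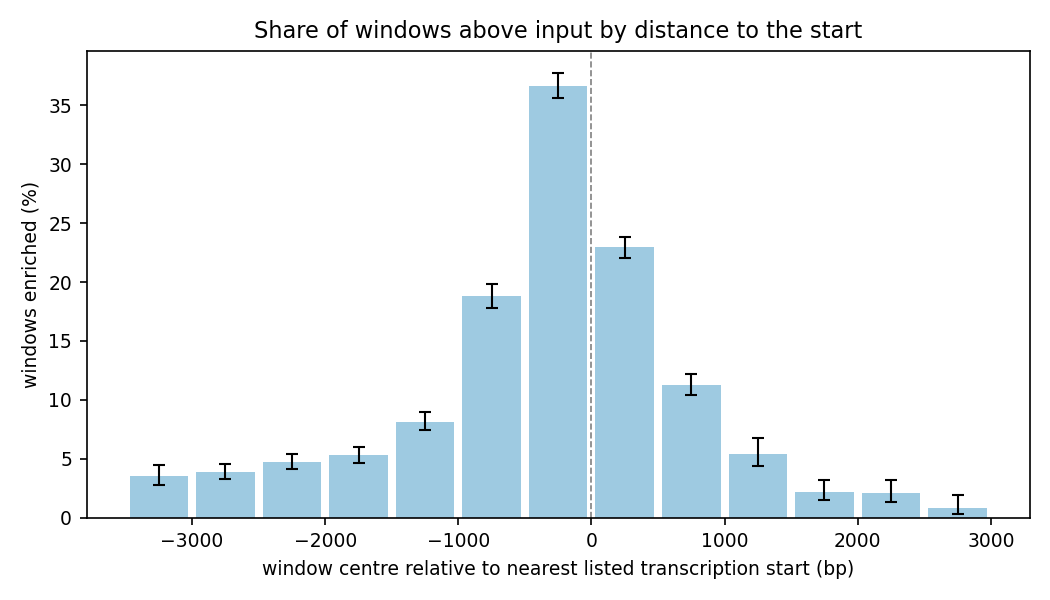
Percent of 500 bp windows called enriched (vertical axis, with 95% Wilson intervals) by distance of the window centre from the nearest listed transcription start in bp (horizontal axis, upstream negative). The share reaches 36.6% in the 500 bp upstream of the start and is 4.72% from -2500 to -2001 bp. The intervals take windows as independent and do not measure the spread between pools.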

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

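The test of the share of mitochondrial probes was chosen only after the result was seen. The 61 probes of the mitochondrial genome, which lie in 1 tiled stretch, were part of the test of all windows but of no gene or list comparison. They were flagged because their ChIP signal was far above input: their median log2 ratio, averaged over the pools, was 1.59, with 1.23 in pool 1, 1.36 in pool 2 and 2.19 in pool 3. All 12 mitochondrial windows were enriched, between 1.10 and 2.03, and are counted among the 8421 enriched windows, of which 8409 were left without them.

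Local binding at a few sites of the tiled stretch would raise a minority of its probes, but 93.4% of them lay above 0.5 in all pools. This share follows in large part from the medians above, so it adds little to them, but such values argue against a few sites as the whole cause. Scanner saturation can raise a ratio only where it caps the input channel, and it would then raise nuclear windows of the same input signal too. The 236 such windows had a median of -0.0306 (quartiles -0.08 and 0.02), which argues against it as well. Pool 3 had 0 saturated input probes on design 2, which carries the mitochondrial probes, and the highest mitochondrial median, 2.19. A higher share of mitochondrial DNA in the ChIP fraction than in the input would largely restate these ratios, not explain them. What would cause it stays open and was not tested, as no array of a control antibody was used. No biological explanation was tested either.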

How the results depend on the processing

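Alternatives with a count by precipitation number, without mitochondrial windows, with loess and pool 1 left out together, and by tiled region were chosen after seeing the data. The 8421 enriched windows became 1328 with ChIP and input unpaired (no replicate block), 4634 at an adjusted p under 0.01, 1700 at a log2 ratio of at least 0.5, and 16092 with loess and pool 1 left out. Leaving out 1 pool gave 4040 to 14029. Leaving out precipitation number 2, 3 or 4 on both designs gave 14029, 5113 and 5402. The 1063 depleted windows became 1713 with normexp, 3390 with loess, 2613 without the dimmest probes, 3594 with an intensity trend and robust prior, 20 unpaired, 205 at an adjusted p under 0.01, 15 at a size of 0.5, 7333 with loess and pool 1 left out, and 160 to 5846 without a pool. The 5634 genes with an enriched window became 1399 unpaired, 1780 at a size of 0.5, and 3447 to 6982 without a pool. The 728 genes with a peak in all 3 pools became 1671 with all deposited peaks, 374 at a false discovery rate of 0.01, 2761 in at least 2 pools, and 749 to 2653 without a pool. The 4 list shifts became 2 with loess, 1 with probe medians, 1 without matching on windows, and 2 to 3 without a pool. Changes from a threshold or from asking for a peak in fewer pools follow from construction; for the others, the rise without pool 1 included, the cause was not tested.

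Of the 8421 enriched windows, 99.4% were also enriched after loess, 94.5% after normexp, 86.5% without the dimmest probes, 96.9% without pool 1, 68.6% without pool 2, 47.1% without pool 3 and 15.8% unpaired. All 71 named genes kept an enriched window with the authors' values, biweight centring, scaling and without pool 1; 46 did with unpaired channels. None reversed where an outcome was available. With 300 bp windows 61 kept the call and 3 lost it, and without the dimmest probes 65 kept it. The rest of the 71 had no outcome in those alternatives. The share of enriched windows within 500 bp of a start stayed between 53.9% and 67.7%. The mean correlation between pools, 0.486, and the mean log2 difference at peaks of another pool, 0.33, moved by less than their spread. The search for the POU1F1 DNA element was not run. Depth is not defined for arrays, and signal over control probes limits the dim promoters.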

Other observations

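The test on genes of other lineages and the exchange of channels were chosen only after the result was seen. Chemoreceptor promoters separated the pools. A deposited peak was mapped to 339 olfactory or vomeronasal receptor genes in pool 1, 11.6% of that pool's named genes, but to 8 in pool 2 and 16 in pool 3. At a false discovery rate of 0.05 or less the numbers were 123, 6 and 6. Across the 2325 windows of these genes the median log2 ratio was 0.12 in pool 1, -0.17 in pool 2 and -0.05 in pool 3, and after loess it was 0.02, -0.10 and -0.05. These windows were dim, with a median log2 input signal of 9.67 against 10.6 over all windows. In pool 1 the probe ratio fell with input signal on both designs (Spearman's rho across probes -0.42 and -0.461), while in pool 2 it was -0.000585 on design 1 and 0.281 on design 2. In pool 3, with 16 such genes, it also fell with input signal on both designs (-0.166 and -0.0918), less than in pool 1. Input is the denominator of the ratio, so noise in the input alone lowers rho, and a negative sign by itself does not show a dye trend. Random-sequence control probes had median ratios of 0.14 and 0.16 in pool 1 on designs 1 and 2. They were -0.09 and -0.26 in pool 2, and -0.01 and -0.04 in pool 3. Probes of the Y chromosome, in pregnant animals, had medians of 0.12, -0.25 and -0.02 in pools 1, 2 and 3. Both follow the order of the chemoreceptor medians, so this difference between pools is not read as POU1F1 binding.

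On chromosome 1, 8 adjoining windows from 24566226 to 24570225 were enriched, between 1.13 and 2.05. They were chosen after their values were seen. The next tested window, from 24571226, was at -0.17 and did not pass. The mitochondrial windows lay between 1.10 and 2.03, close to the range of these 8. Whether the probes of these windows also match mitochondrial DNA was not tested, since the genome sequence was not used here. The 8409 enriched windows left without mitochondrial windows still include these 8, so their ratios are not read as POU1F1 binding.

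Ribosomal protein and oxidative phosphorylation genes with an enriched window numbered 84, with 83 distinct best windows at a median log2 ratio of 0.42. Dye bias that follows signal was predicted to bring this median under 0.1 after loess. The median stayed at 0.42 (quartiles 0.34 and 0.56) with all 83 windows still called. These windows had been called on the same ratios. The dimmest 10% of probes had mean ratios of 0.24, -0.06 and 0.06 in pools 1, 2 and 3 on design 1. On design 2 they were 0.30, -0.23 and 0.01. Trends of mixed sign leave loess little to take from a mean of 3 pools, so the fall could hardly occur. The values show only that the trend with signal adds little to this median. Chromatin of active promoters, recovered without POU1F1, may give the same pattern; 7.14% of genes of the other anterior pituitary lineages were named in a peak list against 86.4% of oxidative phosphorylation genes. Those lineage genes are active in a minority of the gland's cells, and not all of them are confined to those lineages. Active chromatin therefore cannot be told apart from POU1F1 at these promoters without a control antibody or the sequence of the windows. Binding of POU1F1 in the cells that express it, the biological explanation, also stays open.

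Pool 1 had fewer peaks than the other pools. At peaks shared by pools 2 and 3, its median was 0.577 times their mean on design 1 and 0.564 times on design 2. Pools 2 and 3, left out in the same way, stood between 0.992 and 1.3 times the others. That comparison is not alike. It rests on 245 to 264 windows that needed a peak in pool 1, against 842 and 969 windows for pool 1. The mean of the others also includes pool 1 there, which raises the ratio if pool 1 is weak. Dye bias in pool 1 was predicted to lift the ratio of pool 1 after loess to 0.9 or more, and the higher of the 2 designs was 0.631. A weaker contrast of ChIP over input in pool 1 was predicted to keep the ratios under 0.7. All 4 lay under 0.7, and the lowest was 0.564. But the windows for pool 1 were chosen for a peak in pools 2 and 3, which raises the mean of those pools. Loess does not remove this, so the ratio could stay low under either explanation. These ratios therefore decide neither dye bias nor a weaker contrast. Whether the tissue or the precipitation differed was not tested.

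For the count of enriched windows, the channels of no pool or of 1 pool can be exchanged in 4 ways, too few for a share under 0.05. The real assignment gave 8421 enriched windows, 1 of the 4 reached that number, and the highest other gave 0 with limma.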
